A study of Mus musculus with 12 samples.

How the data were processed

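Macrophages were sorted from bone marrow nucleated cells of MSC-treated tibias and untreated femurs of 2 mice with a C57BL/6 background, per the labels. RNA was isolated with a column micro kit that includes DNase digestion on the column, and libraries were made with a Vazyme VAHTS mRNA-seq kit, per the labels' protocols. The deposited table holds 1 column of raw read counts per library, in whole numbers, with no scaling by the authors that the values show. Per the submitters' processing notes, the genome build was mm10 and the tools named were bcl2fastq, HISAT2, featureCounts, Subread and DESeq2. Their versions, settings, order, strand handling and annotation release are not given in the sources used here. Without the strand setting, reads of overlapping genes and of antisense partners cannot be told apart, and reads of near-identical copies can be split between them.

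The table had 23420 gene rows, of which 16286 held a count in at least 1 library. All 12 sample columns were matched to their samples by title, and 0 columns were left unmapped. A spreadsheet had turned 27 gene names into dates, and 2 of these names stand for 2 rows each. These rows took up to 0.194% of a library's reads and are not named here. Total counts per library ran from 9773455 to 14869150. The 10 most abundant genes took 6.29 to 7.50% of the counts, and the ribosomal RNA gene Rn45s took 0.0586 to 0.532%. Among counts from 1 to 10, 69.8% were even (67.3 to 71.3% per library), and counts of 2 were 3.26 times as frequent as counts of 1 (9755 against 2995). Most fragments thus appear as 2 counts, as when both ends of a read pair are counted. A count of 0 in a library therefore allows up to 3 fragments at 95% confidence, which are 6 counts or 0.404 to 0.614 CPM. Counting intervals for single genes were likewise computed on counts divided by 2, and a fit on halved counts was added as an alternative after the data were seen. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

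Libraries were grouped by bone and mouse from their titles. The 3 libraries of 1 bone of 1 mouse were compared before use. Their counts differed by more than sampling noise (chi-square per gene of 2.74 to 6.29, and 1.37 to 3.15 on halved counts), against 5.42 to 10.1 between bones of 1 mouse and 10.5 to 22.3 between mice for the same bone, so they were kept as separate libraries. The labels do not say whether they come from separate sorts or from 1 RNA sample. The model therefore measures the spread between libraries, and the same comparison was repeated on counts summed per mouse and bone, where the animal is the unit.

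Counts were analysed in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by TMM. Genes were kept by filterByExpr with its minimum count of 10 over the 4 groups of mouse and bone, which left 11806 genes holding at least 99.9% of the reads of every library. The comparison of tibia with femur used edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) with the mouse as a term, on all 12 libraries. The contrasts within mouse 7, within mouse 19, and of the difference between them came from a model with 1 mean per mouse and bone. All tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 5.51% with 1 mean per mouse and bone and 6.26% with the mouse as a term. Log2 fold changes carry an approximate standard error, the absolute change divided by the square root of the test's F value. CPM values were computed from the counts over TMM-scaled library sizes and are given as mean ± SD over 6 libraries. Coordinates come from the GRCm38.p6 reference table, the assembly that mm10 names.

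A total of 38 gene lists were written before the data were examined, 13 of them for other cell types. They cover classical and alternative activation, resident macrophages, efferocytosis, monocytes, antigen presentation, interferon and NF-kB responses, metabolism, lysosome, secreted factors, matrix, chemokines, cell cycle, stress, ribosomal proteins and marrow cell types. They name 846 genes, of which 833 were matched to the table, 15 of them under another symbol, and 690 were tested. Each list was tested with camera in limma 3.58.1 on voom values, with the preset correlation of 0.01 between genes, the mouse as a term and adjustment over the lists. Over both mice and for the difference between them, camera was repeated with a correlation estimated per list, and fry was run over both mice. Within each mouse camera was run with the preset correlation only, on contrasts fitted to all 12 libraries unless 1 mouse alone is named. Fry asks whether a list's genes move on balance 1 way and does not compare them with other genes. It called 12 lists, and 32 when changes in either direction count.

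Genes are named by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest log2 fold changes among genes past the threshold, with the same sign in both mice and at least 10 CPM in the higher group, without predicted models, immunoglobulin and T cell receptor segments and date names. It adds 10 macrophage genes named whatever their values. For each list it takes up to 4 members with the lowest adjusted p, or, where fewer than 2 pass, up to 2 of the most abundant. For the difference between the mice it takes the 5 highest and 5 lowest genes. This gave 127 genes, of which the text gives examples; some of the others are not reported here. Those shown as having changed over both mice kept that call without each single library unless the libraries are named. Of the genes of the rule, 24 lost a call without at least 1 library. The call of the difference between the mice was repeated in this way only for the genes taken for that difference. For single genes, calls within 1 mouse, calls on sums and the difference of the other genes were not repeated without single libraries.

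Alternatives fixed before the data were examined were median-of-ratios scaling, no low-count filter, a filter of 5 CPM in at least 3 libraries, library sizes without the 50 most abundant genes, DESeq2 1.42.0, limma-voom, a test against a fold of 1.5 (glmTreat), each library left out in turn, no mouse term, a block on the library number, 1 mean per mouse and bone, a random block for the bone of a mouse, sums per animal, and each mouse alone. Other splits of the libraries were drawn with a fixed seed, 100 of the 462 splits into 6 and 6. The scripts were tested on simulated data in which 200 genes changed by known folds. Over both mice, 62% of genes changed by 1.25-fold, 88% at 1.5-fold, 92% at 2-fold and 100% at 4-fold were recovered, with 7 calls among unchanged genes of 11690. On sums per animal the shares were 66, 90, 92 and 100%, with 11 such calls. In mouse 7 they were 38, 78, 88 and 100%, and in mouse 19 48, 78, 76 and 94%. For the difference between the mice they were 16, 66, 70 and 94% of genes, over 11692 genes. The simulated genes changed alike in both mice, or in mouse 19 only for the difference, with no spread of the effect between animals. These shares and calls therefore do not measure what the fits recover, or call falsely, over animals. A simulated list of 20 genes raised by 1.25-fold had a camera adjusted p of 3.5e-96 and 0 of the other lists were called. The genes of the simulated lists were drawn independently of each other. These values therefore do not measure false calls in lists whose genes move together, such as cell cycle (estimated correlation 0.654).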

Results

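The data are bulk RNA-seq libraries of macrophages sorted from the bone marrow of C57BL/6 mice. The tibias had been treated with mesenchymal stromal cells (MSCs), the supporting fibroblast-like cells of the marrow, and the femurs of the same animals were left untreated. The labels call the cells from the treated tibia MSC-educated macrophages, and the series title places the study in leukaemic bone marrow. Whether these animals carried leukaemia, and how and when the cells were given, is not given in the sources used here. There were 6 libraries from MSC-treated tibias and 6 from untreated femurs, made as 3 libraries per bone from each of 2 mice, numbered 7 and 19 in the sample titles. Every treated bone was a tibia and every untreated bone a femur, so treatment and bone change together in each comparison. Total counts ran from 9773455 in femur library 1 of mouse 19 to 14869150 in tibia library 1 of mouse 19. Between 13524 and 13902 genes had at least 1 count in a library, and 11806 genes were tested. In a principal component analysis the first component (32.6% of the variance) separated the mice and the second (14.3%) separated the bones.

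The first comparison asked which transcripts differ between macrophages of the treated tibia and those of the untreated femur. Arg1, which encodes arginase 1, the enzyme that splits arginine into ornithine and urea, rose from 0.215 ± 0.209 CPM (counts scaled to library size) in the femur to 34.1 ± 12.7 in the tibia (mean ± SD, n = 6 libraries each). Spp1, the gene of the secreted matrix protein osteopontin, rose from 12.5 ± 1.73 to 82.1 ± 14.99 CPM. Dab2, an endocytic adaptor, rose from 2.81 ± 0.84 to 23.7 ± 4.68 CPM, and Spint1, a membrane-bound inhibitor of serine proteases, rose from 3.23 ± 1.24 to 25.9 ± 10.2 CPM. The acute-phase gene Saa3 rose from 10.8 ± 2.53 to 56.5 ± 16.0 CPM. In all 5 genes each of the 6 tibia libraries lay above every femur library of its own mouse.

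As log2 fold changes with their standard errors, tibia over femur, the edgeR quasi-likelihood test gave 7.14 ± 0.23 for Arg1 (Benjamini-Hochberg adjusted p = 7.8e-17), 3.04 ± 0.15 for Dab2 (7.6e-13), 2.98 ± 0.12 for Spint1 (7.3e-15) and 2.70 ± 0.07 for Spp1 (2.0e-19). Arg1 rested on 2718 counts in the tibia and 17 in the femur, a ratio of 152 with a 95% interval of 75.4 to 314 that covers counting error only. Femur library 3 of mouse 7 held 0 Arg1 counts, which allows up to 0.439 CPM. Among genes with at least 10 CPM in the higher group and the same sign in both mice, the next by size were Saa3 (2.33 ± 0.15), the tetraspan membrane protein gene Emp1 (1.83 ± 0.14), the membrane-anchored matrix protease gene Mmp14 (1.47 ± 0.11), the interferon-induced Ifitm1 (1.38 ± 0.09), the complement receptor gene C3ar1 (1.35 ± 0.08) and the scavenger receptor gene Stab1 (1.33 ± 0.12). All 10 of these genes were higher in 6 of 6 tibia libraries and passed the same test on counts summed per animal. Their call over the libraries was kept without any 1 of the 12 libraries. On sums only 9 genes were higher without tibia library 3 of mouse 7, so not all 10 kept the call on sums there. In the GRCm38.p6 annotation Arg1 lies on chromosome 10 from 24915207 to 24927470, Spp1 on chromosome 5 from 104435111 to 104441053, Dab2 on chromosome 15 from 6299788 to 6440715 and Spint1 on chromosome 2 from 119237360 to 119249535. The counts are per gene and are not divided among exons.

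**Figure D1:**
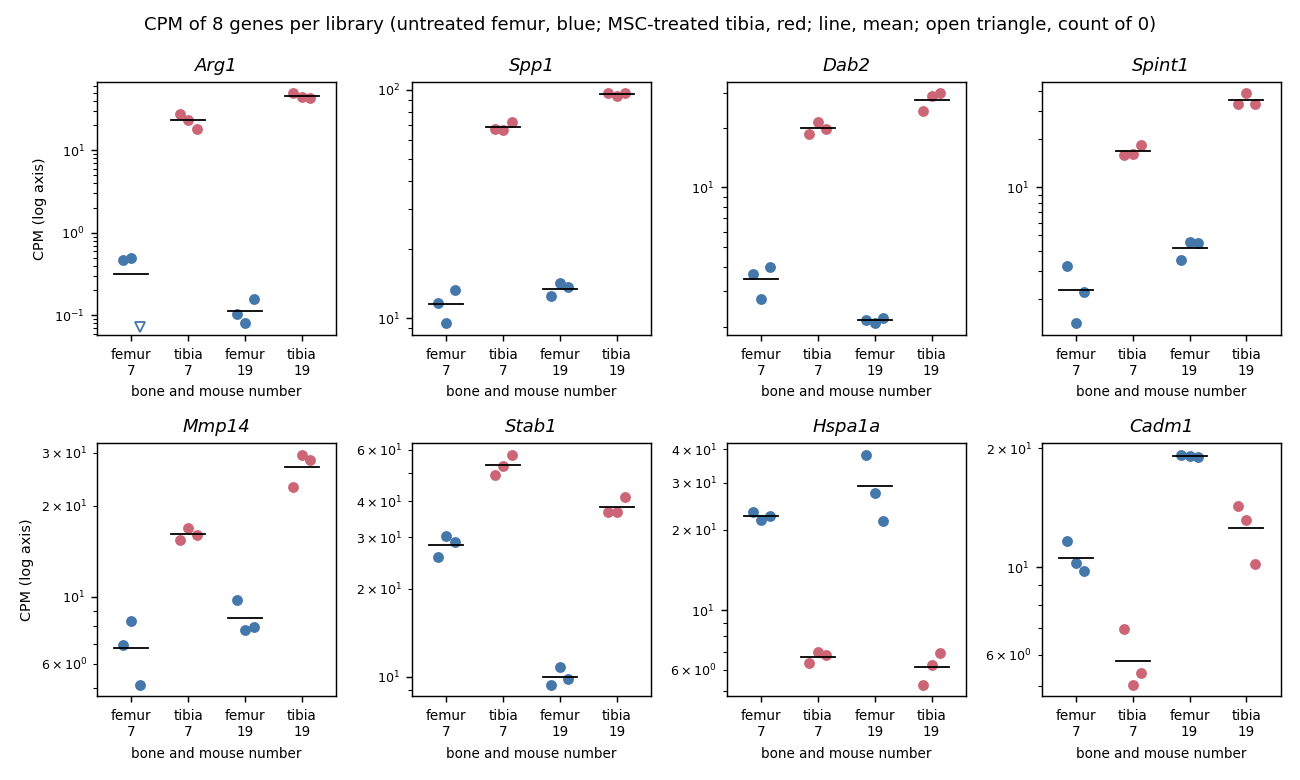
CPM (log axis) of 8 genes in each of the 12 libraries, by bone and mouse, with untreated femur in blue, MSC-treated tibia in red, a line at the mean of 3 libraries and an open triangle for a count of 0. Arg1 ran from 18.3 CPM upwards in the tibia and up to 0.491 CPM in the femur, while Hspa1a and Cadm1 lay lower in the tibia of both mice.

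Other genes were lower in the tibia. The stress-induced heat shock genes Hspa1a and Hspa1b fell from 25.8 ± 6.42 to 6.43 ± 0.65 CPM and from 35.8 ± 4.91 to 9.17 ± 2.49 CPM, log2 changes of -1.99 ± 0.12 and -1.98 ± 0.12 (edgeR adjusted p = 5.4e-11 and 4.4e-11; lower in 6 of 6 tibia libraries). These are near-identical copies whose reads can be assigned to either, so their separate values are uncertain. Cadm1, an adhesion molecule of dendritic cells, fell by 0.72 on the log2 scale (SE 0.11, adjusted p = 1.2e-04), and Beta-s, an adult beta-globin gene with close relatives in its cluster, fell by 0.67 (SE 0.10, adjusted p = 8.5e-05). Gabbr1, a subunit of the GABA-B receptor, fell by 0.62 (SE 0.10). All of these passed on sums per animal as well.

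The C-type lectin gene Cd209a fell by 0.77 (SE 0.16, edgeR adjusted p = 0.0033, 0.114 on sums per animal). Eps8l1, related to a regulator of actin, fell by 0.56 (adjusted p = 0.0035, 0.123 on sums), and Ear1, an eosinophil ribonuclease of a family with close copies, fell by 0.54 (lower in 5 of 6 tibia libraries, 3.2e-04, 0.0638 on sums). Igj, the antibody joining chain gene, fell by 0.71 (adjusted p = 0.0251, 0.0097 on sums). The Igj call was lost without tibia library 1 or 3 of mouse 7, tibia library 3 of mouse 19, femur library 3 of mouse 7, or femur library 1 or 3 of mouse 19, with adjusted p from 0.0557 to 0.0806. Car2, carbonic anhydrase 2, fell by 0.53 (adjusted p = 0.0398, 0.167 on sums). The Car2 call was lost without tibia library 1 or 3 of mouse 7, tibia library 1 or 2 of mouse 19, femur library 1 of mouse 7, or femur library 1 or 2 of mouse 19, with adjusted p from 0.058 to 0.133.

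A set of 10 macrophage genes was to be named whatever their values, and Arg1 is 1 of them. Nos2, the inducible nitric oxide synthase that competes with arginase for arginine, rose from 0.256 ± 0.256 to 1.63 ± 1.59 CPM (log2 2.53 ± 0.42, edgeR adjusted p = 4.7e-04, 0.0374 on sums per animal). It rested on 131 counts in the tibia and 19 in the femur, a ratio of 6.55 (95% interval of 3.20 to 13.7). Most of these counts came from mouse 19, where it rose from 0.438 to 3.03 CPM (adjusted p = 2.6e-04). In mouse 7 it did not pass (0.399), on 9 against 3 counts (ratio 3.05, 0.417 to 26.7), and the difference between the mice did not pass either (0.771). Il1b, which encodes the inflammatory cytokine interleukin-1 beta, had a log2 change of 0.34 ± 0.10 (higher in 4 of 6 tibia libraries, adjusted p = 0.0464, 0.419 on sums). The Il1b call was lost without tibia library 3 of mouse 7 or any 1 of 5 libraries of mouse 19 (tibia libraries 1 and 2 and femur libraries 1, 2 and 3), with adjusted p from 0.069 to 0.125. Il1b passed in mouse 19 (0.77, 5.7e-07) and not in mouse 7 (-0.04, 0.842). The mannose receptor gene Mrc1 (0.34 ± 0.11, adjusted p = 0.0605) missed the threshold, and passed it without tibia library 3 of mouse 7 (0.0304) or femur library 2 of mouse 7 (0.0214). The other genes did not pass: Tgfb1, transforming growth factor beta 1, at 348 CPM in both bones (adjusted p = 0.993), Tnf at -0.05 (0.827), the anti-inflammatory cytokine gene Il10 at -0.46 (0.416), the haemoglobin scavenger receptor gene Cd163 at 0.34 (0.410), Emr1, which encodes the F4/80 antigen, at -0.05 (0.561), and the macrophage growth factor receptor gene Csf1r at 0.03 (0.745). For Csf1r this averages opposite changes, -0.14 in mouse 7 (adjusted p = 0.0071) and 0.21 in mouse 19 (1.9e-04), and Emr1 was lower in mouse 7 (-0.22, 3.2e-04) and did not pass in mouse 19 (0.12, 0.0741). Mrc1 passed in mouse 19 (0.65, 0.0012) and not in mouse 7 (0.03, 0.927). The difference between the mice passed for Il1b, Mrc1, Emr1 and Csf1r.

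Across all genes, edgeR called 414 higher and 436 lower of 11806 at an adjusted p under 0.05. The median change among them was 0.205 on the log2 scale without its sign, and 36 of the higher and 11 of the lower genes changed by at least 2-fold. On counts summed per animal, 48 were higher and 17 lower, and 45 and 17 of these were also called over the libraries. The p-values of the first test measure the spread between libraries, and the 3 libraries of a bone are not separate animals. The lower count was 279 without tibia library 3 of mouse 7 and 283 without tibia library 2 of mouse 19. On sums, leaving out a library before summing moved the higher and lower counts to 26 and 4 (tibia library 1 of mouse 7), 134 and 55 (tibia 2 of mouse 7), 9 and 2 (tibia 3 of mouse 7), 102 and 45 (tibia 1 of mouse 19), 11 and 2 (tibia 2 of mouse 19), 137 and 57 (femur 1 of mouse 7), 21 and 5 (femur 2 of mouse 7), 24 and 3 (femur 3 of mouse 7) and 30 and 7 (femur 2 of mouse 19), and the lower count to 11 without tibia 3 or femur 3 of mouse 19.

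Gene lists fixed before the data were examined were counted in the same test. Each list member named here as rising or falling was on that side of the femur mean of its own mouse in 6 of 6 tibia libraries. In the matrix remodelling list 7 of 18 tested members rose and 4 fell (8 and 4 adjusted over the list alone). Spp1 and Mmp14 are described above, Tgfbi, a secreted adhesion protein, rose by 0.43 ± 0.03, and Mmp9, a gelatinase, fell by 0.36. The list was higher by camera (median 0.10, adjusted p = 7.8e-04) and lost its call at adjusted p = 0.318 with an estimated correlation. With the preset correlation it passed in mouse 19 (2.8e-07) and not in mouse 7 (0.0680). In arginine and polyamine metabolism 4 of 15 rose and 1 fell (5 and 1 adjusted over the list alone). Besides Arg1 and Nos2, which are described above, Gatm, which makes the creatine precursor guanidinoacetate, rose by 0.51 ± 0.07. The list had a median of 0.02 (camera adjusted p = 0.0015, and adjusted p = 0.0654 with an estimated correlation). With the preset correlation camera gave 9.0e-04 in mouse 19 and 0.0586 in mouse 7, and the difference between the mice did not pass (0.512). Among 14 secreted growth and repair factors 2 rose, Spp1 and the angiogenic factor gene Vegfa (0.49 ± 0.08, 0.0690 on sums), and 2 adjusted over the list alone (camera adjusted p = 0.0664).

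The macrophage activation lists moved both ways. Of 23 alternative activation genes 5 rose and 7 fell (7 and 9 adjusted over the list alone). Arg1, Stab1 and the transglutaminase gene Tgm2 (1.01 ± 0.15, adjusted p = 1.7e-04, 0.0732 on sums) rose, whereas the chitinase-like gene Chi3l3 fell by 0.20 (SE 0.02, adjusted p = 9.7e-06, 0.196 on sums). Its median was -0.00063, its mean 0.42 and its camera adjusted p 0.932. Of 18 classical activation genes 4 rose and 1 fell (5 and 1 adjusted over the list alone). Nos2 and Socs3, a feedback inhibitor of cytokine signalling (0.50 ± 0.11, adjusted p = 0.0047), rose. The list's median of -0.05 and mean of 0.18 differed in sign (camera adjusted p = 0.567). Socs3 did not pass on sums (0.119).

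Efferocytosis and phagocytosis genes, which serve the uptake of dead cells, held 6 higher and 3 lower of 28 (7 and 3 adjusted over the list alone; median 0.03, camera adjusted p = 0.176, and 0.034 without femur library 1 of mouse 7). Mertk, a receptor for apoptotic cells, rose by 1.01 ± 0.13 (adjusted p = 2.9e-05, 0.0163 on sums) and the integrin gene Itgb5 by 0.56 ± 0.07, whereas Itgb3, another integrin gene, fell by 0.46 (SE 0.05). In the resident bone marrow and erythroblastic island list 4 of 24 rose and 0 fell (4 and 4 adjusted over the list alone), among them the transcription factor gene Maf (0.58 ± 0.11) and the haem-degrading enzyme gene Hmox1 (0.32 ± 0.06); its median was -0.02 with a camera direction of higher (adjusted p = 0.759). Maf and Hmox1 did not pass on sums (0.122 and 0.178). Lysosome genes had 5 higher and 0 lower of 33 (6 and 0 adjusted over the list alone; median 0.02), with the protease genes Ctsl (0.60 ± 0.05) and Lgmn (0.53 ± 0.07) rising. The lysosome list missed the threshold by camera (adjusted p = 0.0664) and passed it without femur library 1 (0.0352) or 3 (0.01) or tibia library 1 (0.0085) or 2 (0.0448) of mouse 7, or femur library 1 (0.0493) or tibia library 3 (0.0463) of mouse 19. The growth factor list above passed without femur library 1 (0.0318) or tibia library 1 (0.0433) of mouse 7. It also passed by camera with the filter of 5 CPM in at least 3 libraries (0.0106), and by fry (adjusted p = 6.0e-05).

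Several lists with small median changes were called higher by camera over both mice. The granulocyte precursor list, described below, was higher as well and by more (median 0.31), and a change in cell shares was not told apart from a change within the macrophages. In oxidative phosphorylation 11 of 37 genes rose and 0 fell (19 and 0 adjusted over the list alone; median 0.10, adjusted p = 2.7e-11, and adjusted p = 0.131 with an estimated correlation). Its respiratory chain members Atp5g1 (0.33 ± 0.06) and Cox5a (0.23 ± 0.04) rose, with 0.0794 and 0.134 on sums. In the unfolded protein response 7 of 20 rose (9 adjusted over the list alone; median 0.12, adjusted p = 1.1e-06, and adjusted p = 0.102 with an estimated correlation), including the chaperone genes Hspa5 (0.17 ± 0.03) and Calr (0.22 ± 0.03), which did not pass on sums (0.237 and 0.117). In hypoxia and glycolysis 7 of 29 rose and 4 fell (11 and 4 adjusted over the list alone; median 0.09, adjusted p = 4.1e-04, and adjusted p = 0.123 with an estimated correlation), with the glycolytic enzyme genes Pgk1 (0.20 ± 0.03) and Tpi1 (0.19 ± 0.03) among those that rose, neither of them passing on sums (0.190 and 0.217). Ribosomal protein genes had 3 higher of 42 (3 adjusted over the list alone; median 0.05, adjusted p = 4.2e-07, and adjusted p = 0.400 with an estimated correlation). Cholesterol synthesis had 2 higher of 24 (5 adjusted over the list alone; median 0.10, adjusted p = 6.7e-04, and adjusted p = 0.330 with an estimated correlation), among them the farnesyl diphosphate synthase gene Fdps (0.35 ± 0.07, 0.217 on sums; in mouse 19 0.11, adjusted p = 0.411). Within the mice, with the preset correlation, the list was higher in mouse 7 (4.3e-08) and did not pass in mouse 19 (0.963). Cell cycle genes had 3 higher of 38 (5 adjusted over the list alone; median 0.07, adjusted p = 3.0e-04, and adjusted p = 0.563 with an estimated correlation), among them Gins2, a DNA replication factor at 0.39 ± 0.10 (0.289 on sums); the Gins2 call was lost without tibia library 2 (0.0562) or femur library 1 (0.059) of mouse 7. The direction of the cell cycle list turned between the animals. It was higher in mouse 7 (median 0.20, camera adjusted p = 2.6e-26) and lower in mouse 19 (-0.07, 8.5e-07). Both values used the preset correlation, while the correlation estimated for this list over both mice was 0.654.

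Monocyte and interferon lists were called lower over both mice, and within the mice they passed as lower in mouse 7 only. For classical monocytes the camera direction was lower in both mice. Their difference between the mice passed with the preset correlation (camera adjusted p = 0.0071) and not with an estimated one (0.161). Within the mice camera used the preset correlation only, while over both mice the estimated correlation was 0.557 for the type I interferon list. In mouse 7 camera gave adjusted p of 3.1e-07 for classical and 5.6e-11 for non-classical monocytes, both lower. The type I (4.5e-19) and gamma (1.0e-07) interferon responses were lower there as well. In mouse 19 the direction turned for non-classical monocytes (median 0.16, adjusted p = 0.0396) and type I interferon (0.20, 2.8e-07), which were higher there, while interferon gamma (0.08, 0.394) and classical monocytes (-0.02, 0.113) did not pass. In the classical monocyte list 7 of 16 fell and 0 rose (7 and 1 adjusted over the list alone), among them the fibronectin gene Fn1 (fell by 0.14, SE 0.03), with 0.429 on sums. Fn1 itself was not lower in mouse 7 only. In 6 of 6 tibia libraries it lay below every femur library of the same mouse. The list median was -0.04 (camera adjusted p = 3.0e-04, and adjusted p = 0.115 with an estimated correlation). In the non-classical monocyte list 3 of 16 fell and 0 rose (3 and 1 adjusted over the list alone; median -0.11, adjusted p = 7.8e-04, and adjusted p = 0.330 with an estimated correlation), including Pou2f2, a transcription factor gene (fell by 0.26, SE 0.05, 0.106 on sums). Type I interferon response genes had 3 lower and 0 higher of 32 (3 adjusted over the list alone; median -0.08, adjusted p = 7.6e-04, and adjusted p = 0.563 with an estimated correlation). Interferon gamma response genes had 3 lower and 0 higher of 25 (5 adjusted over the list alone; median -0.10, adjusted p = 0.0011, and adjusted p = 0.360 with an estimated correlation), with the serine protease inhibitor gene Serpina3g falling by 0.55 (SE 0.11, 0.189 on sums).

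The other lists of macrophage state were not called. Antigen presentation by MHC class II had 1 higher of 16, Lgmn, the same count adjusted over the list alone (median -0.02, camera direction higher, adjusted p = 0.710). NF-kB and TNF response had 3 higher and 1 lower of 23 (3 and 2 adjusted over the list alone; median -0.02, mean 0.07, adjusted p = 0.844). Lipid handling and liver X receptor targets had 7 higher and 2 lower of 24 (9 and 6 adjusted over the list alone; median -0.03, mean 0.07, adjusted p = 0.389), with the lipid receptor gene Trem2 (0.33 ± 0.06) and Apoe, apolipoprotein E (0.50 ± 0.10), rising. Neither passed on sums (0.0559 and 0.217), and Apoe did not pass in mouse 7 (0.06, adjusted p = 0.430). Iron and heme handling had 4 higher and 1 lower of 22 (6 and 1 adjusted over the list alone; median 0.01, adjusted p = 0.176). Chemokines had 2 higher of 14, also adjusted over the list alone, the membrane-bound Cxcl16 (1.01 ± 0.12) and the platelet factor gene Pf4 (1.55 ± 0.31, 0.0721 on sums), with a median of -0.01, a mean of 0.25 and an adjusted p of 0.331. Immediate early and dissociation stress genes had 1 higher and 3 lower of 24, also adjusted over the list alone (median 0.05, mean -0.11, adjusted p = 0.570, and 0.0292 without femur library 3 of mouse 19). Beside Hspa1a and Hspa1b the member that fell was the constitutive chaperone gene Hspa8 (fell by 0.14, SE 0.03, 0.434 on sums). The p53 targets and cell death list had 1 higher of 16, also adjusted over the list alone (median -0.04, adjusted p = 0.628).

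Lists of other marrow cell types were counted in the same way, since a sort can hold some of these cells. Granulocyte precursor genes had the highest median: 12 of 16 rose and 0 fell (13 adjusted over the list alone; median 0.31, camera adjusted p = 1.1e-15, and adjusted p = 0.0498 with an estimated correlation). The membrane protein gene Ms4a3 rose from 42.0 ± 13.2 to 67.7 ± 18.1 CPM (0.69 ± 0.08), and the granule protease genes Elane (0.51 ± 0.07) and Prtn3 (0.44 ± 0.06) rose as well, all 3 also on sums (2.9e-04, 0.0089 and 0.0378). Conventional and plasmacytoid dendritic cell genes moved the other way, with 5 of 17 lower and 0 higher (6 adjusted over the list alone; median -0.31, adjusted p = 4.7e-06, and adjusted p = 0.0171 with an estimated correlation). Cadm1, Cd209a and the integrin gene Itgax (fell by 0.33, SE 0.04, 0.0455 on sums) were among them. These were the only lists called with the preset correlation that also passed with an estimated one, the precursor list narrowly. No list was tested on sums per animal, so camera's p-values measure the spread between libraries. The fits over both mice with an estimated correlation were not repeated without single libraries. All 16 and 17 tested members were also counted in the femur libraries, and 3 and 4 of them stand in another list.

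Neutrophil genes had 8 higher and 5 lower of 25 (10 and 5 adjusted over the list alone; median 0.07, adjusted p = 0.0202, and adjusted p = 0.563 with an estimated correlation), with the decoy receptor gene Il1r2 rising (0.57 ± 0.09) and the resistin-like gene Retnlg falling by 0.29 (SE 0.05), with 0.0695 and 0.0745 on sums. The neutrophil call was lost without femur library 1 (0.109) or 2 (0.165) or tibia library 1 (0.0617) or 2 (0.0964) of mouse 19. It was also lost with the filter of 5 CPM in at least 3 libraries (camera adjusted p = 0.195). Erythroid genes had 1 higher and 3 lower of 21 (1 and 4 adjusted over the list alone; median -0.47, adjusted p = 4.2e-04, and adjusted p = 0.330 with an estimated correlation), with Beta-s and the red cell anion exchanger gene Slc4a1 (fell by 0.79, SE 0.15, 0.0839 on sums) among the lower. The erythroid call was lost without tibia library 1 of mouse 19 (0.0545). Endothelial genes had 2 lower of 9 (4 adjusted over the list alone; median -0.34, adjusted p = 0.0110, and adjusted p = 0.115 with an estimated correlation). B cell genes had 0 called of 13 by edgeR (1 higher and 2 lower adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.0202, and adjusted p = 0.378 with an estimated correlation). The B cell call was lost without femur library 1 (0.0836) or 3 (0.0713) or tibia library 3 (0.0985) of mouse 7. The same stricter filter ended it as well (camera adjusted p = 0.139). Basophil, mast cell and eosinophil genes had 3 lower of 18 (4 adjusted over the list alone; median -0.08, adjusted p = 0.0225, and adjusted p = 0.360 with an estimated correlation), a call lost without femur library 2 (0.0793) or 3 (0.13) or tibia library 3 (0.129) of mouse 19. Within the mice, camera with the preset correlation called the neutrophil, erythroid, endothelial and basophil lists in mouse 19 (4.0e-06, 2.9e-06, 0.0285 and 0.0017). These were not called in mouse 7 (0.473, 0.638, 0.189 and 0.586). The B cell list was called in mouse 7 (0.0073) and not in mouse 19 (0.895). By camera the difference between the mice did not pass for the endothelial (0.720), basophil (0.191) and B cell (0.0735) lists. It passed for the neutrophil (1.1e-05) and erythroid (0.0208) lists, but not with an estimated correlation (0.240 and 0.411).

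The remaining cell type lists were not called by camera. Fry called the mesenchymal stromal cell and osteoblast list (adjusted p = 0.0492) and the stem and progenitor cell list (0.0122) lower. Mesenchymal stromal cell and osteoblast genes had 0 higher and 0 lower of 12 by edgeR (1 lower adjusted over the list alone; median -0.12, adjusted p = 0.310), with the intermediate filament gene Vim at 0.02 and the osteoblast transcription factor gene Runx2 at -0.13. Osteoclast genes had 2 higher and 3 lower of 13 (3 and 3 adjusted over the list alone; median -0.02, mean 0.09, adjusted p = 0.628), with the fusion gene Ocstamp rising (1.12 ± 0.22, 0.0974 on sums) and Itgb3 and Mmp9 falling. Megakaryocyte and platelet genes had 2 higher and 1 lower of 11, also adjusted over the list alone (median -0.18, mean 0.10, adjusted p = 0.947), the higher ones being Pf4 and the matrix glycoprotein gene Thbs1 (0.96 ± 0.13). Plasma cell genes had 2 lower of 7 (1 higher and 2 lower adjusted over the list alone; median -0.38, adjusted p = 0.404), Igj and the surface receptor gene Slamf7 (fell by 0.51, SE 0.11, 0.112 on sums). Stem and progenitor cell genes had 3 lower of 14 (1 higher and 3 lower adjusted over the list alone; median -0.10, adjusted p = 0.176, and 0.0429 without femur library 1 of mouse 19). T cell and natural killer cell genes had 0 called of 12 by edgeR, also adjusted over the list alone (median -0.28, adjusted p = 0.270).

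The comparison within each animal asked whether the differences hold in both mice. In mouse 7 Arg1 changed by 6.12 on the log2 scale and in mouse 19 by 8.51, on 914 against 13 counts (ratio 71.5, 95% interval 32.0 to 166) and 1804 against 4 counts (ratio 398, 110 to 3290). Spp1 rose by 2.58 and 2.82, Spint1 by 2.89 and 3.05, Hspa1a fell by 1.74 and 2.23, and Ms4a3 rose by 0.73 and 0.66. Each passed edgeR's quasi-likelihood test in both mice. In mouse 7, 516 genes were higher and 633 lower in the tibia, and in mouse 19, 349 and 261. Among them 85 were higher in both mice and 74 lower in both, where independent lists would share 15.3 and 14.0. A further 58 were called in opposite directions. The number that independent lists would give for opposite calls was not computed, so the overlap does not show that disagreement is rare. Across all genes, which are not independent replicates, the log2 changes of the mice correlated at r = 0.297.

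Single libraries moved these counts. The higher and lower counts of mouse 7 were 314 and 387 without tibia library 3, 315 and 409 without femur library 1, and 317 and 381 without femur library 2 of that mouse. The counts of mouse 19 were 226 and 116 without its tibia library 1, and its lower count was 135 without tibia library 2, 137 without femur library 1, 164 without femur library 2 and 170 without femur library 3.

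**Figure D2:**
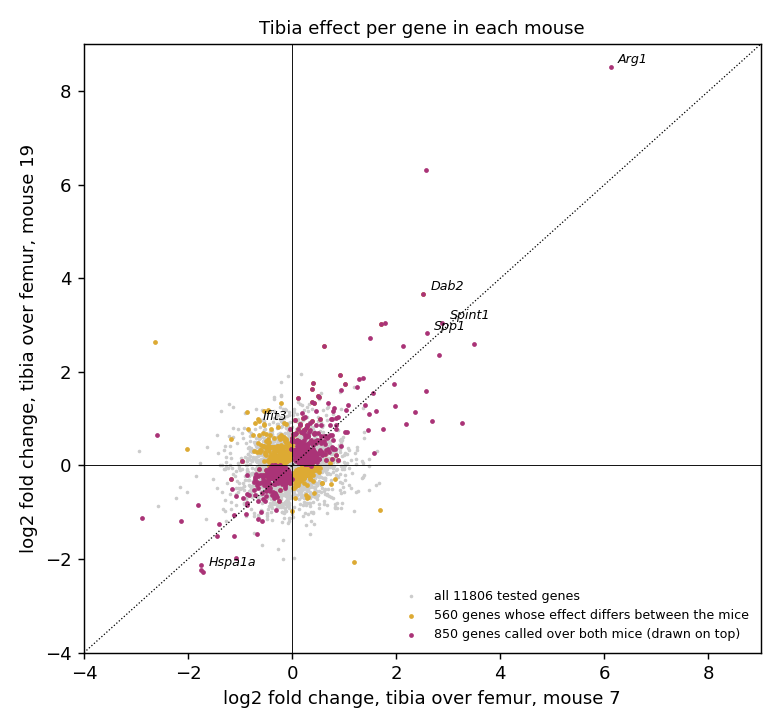
Fitted log2 fold change, tibia over femur, of each of 11806 tested genes in mouse 7 (x axis) and mouse 19 (y axis), with genes whose effect differed between the mice in yellow and genes called over both mice in magenta, drawn on top. Arg1 stands at 6.12 and 8.51, and Ifit3 lies on opposite sides of 0 at -0.71 and 0.90.

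The last comparison tested the difference of the tibia effect between these animals. The interferon-induced genes Cxcl10 and Ifit3 were at -0.85 and -0.71 in mouse 7 and at 0.78 and 0.90 in mouse 19, differences of 1.64 and 1.61 (edgeR adjusted p = 0.0018 and 1.2e-04). The microtubule-associated gene Tppp3 (1.54), Tgm2 (1.38) and the cholesterol exporter gene Abca1 (1.33) were also more positive in mouse 19. Epx and Prg2, granule proteins of eosinophils, were at 0.74 and 0.57 in mouse 7 and -0.39 and -0.38 in mouse 19 (differences of -1.13 and -0.94), and the histidine ammonia-lyase gene Hal (-0.90), Nrg2, a neuregulin (-0.97), and Chn2, a Rac regulator (-0.97), were more negative in mouse 19. The Chn2 call (adjusted p = 0.0179) was lost without tibia library 2 of mouse 7 (0.062), tibia library 1 (0.0518) or 3 (0.0516) of mouse 19, femur library 2 of mouse 7 (0.052) or femur library 3 of mouse 19 (0.0643). Dab2, Saa3, Ifitm1 and Stab1 rose in both mice and by more in mouse 19 (differences of 1.16, 1.31, 0.71 and 1.01). Among the genes named above, Cd209a, Emr1, Fdps and Hspa8 passed in mouse 7 and not in mouse 19. Ear1, Il1b, Mrc1, Socs3, Maf, Hmox1, Apoe and Il1r2 passed in mouse 19 and not in mouse 7. For all of these genes the difference passed. In all, 341 genes had a more positive and 219 a more negative effect in mouse 19, and 468 of these 560 had opposite signs in the mice. With 2 mice this compares these animals only. The test does not tell in which bone the mice differ. Maf stood at 35.0 and 35.5 CPM in the tibia of mouse 7 and mouse 19, and at 30.3 and 17.6 in the femur. Itgb5 stood at 116 and 114 CPM in the tibia and at 95.3 and 63.5 in the femur. For Ifitm1 it was the tibia that differed, with 47.9 and 81.8 CPM against 23.6 and 24.5 in the femur. How many genes go each way was not counted.

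Whole lists also differed between the mice by camera. Type I interferon response genes had a median of -0.29 in mouse 7 and 0.20 in mouse 19 (adjusted p = 7.8e-27, and adjusted p = 0.0031 with an estimated correlation). Antigen presentation by MHC class II went from -0.22 to 0.21 (6.4e-17, and adjusted p = 0.0075 with an estimated correlation), and classical activation from -0.13 to 0.37 (9.8e-08, and adjusted p = 0.0087 with an estimated correlation). Cell cycle genes went the other way, from 0.20 to -0.07 (1.7e-36, and adjusted p = 0.0031 with an estimated correlation), as did cholesterol synthesis, from 0.27 to -0.01 (5.7e-07, and adjusted p = 0.0035 with an estimated correlation). Of 38 lists, 21 differed between the mice, 12 of them with an estimated correlation. The granulocyte precursor and dendritic cell lists had medians of 0.28 and -0.31 in mouse 7 and 0.25 and -0.30 in mouse 19, and their difference between the mice did not pass (adjusted p = 0.618 and 0.253).

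**Figure D3:**
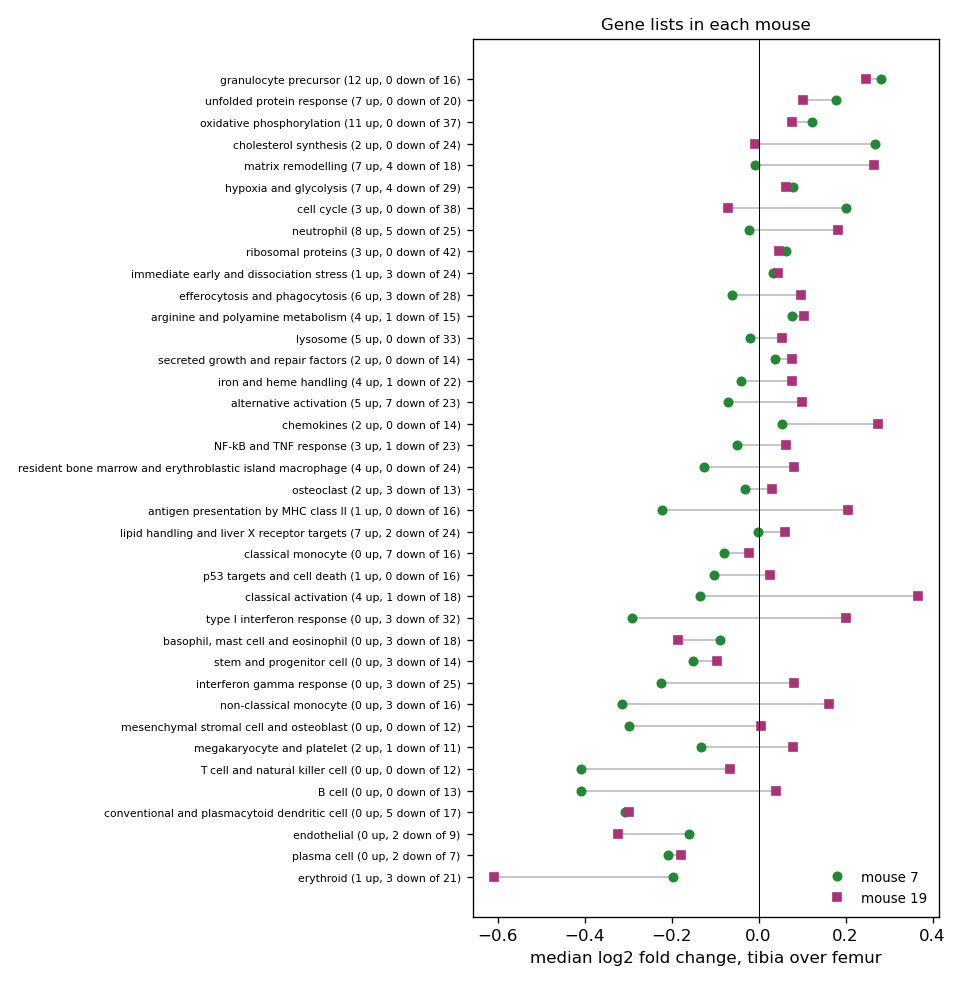
Median log2 fold change, tibia over femur, of the tested members of each of 38 gene lists in mouse 7 (circles) and mouse 19 (squares), with the number of members called higher (up) and lower (down) over both mice beside each name. The granulocyte precursor list lies at 0.28 and 0.25 in both mice, while the type I interferon list lies at -0.29 and 0.20.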

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

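Counting splits of the libraries, leaving out single libraries and the open questions of untreated tibias and of sorting were set out before the results were seen, and the tests of stromal, osteoclast and precursor transcripts, of the gap between lists, of exchanged labels and of whole bones were chosen after them. The sort for macrophages would remove cells of other types, and its gate is not given in the sources used here.

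Arg1, Spp1, Dab2, Spint1 and Mmp14 rose in the tibia by 161 CPM together. RNA carried over from the transferred stromal cells would bring their abundant transcripts, but 6 of these (Col1a1, Col1a2, Col3a1, Sparc, Bgn and Dcn) rose by 0.603 CPM together, from 1.77 to 2.37, against 69.7 CPM for Spp1 alone, which argues against it. More osteoclasts among the sorted cells would raise Acp5 and Ctsk, which together moved by -1.35 CPM (95% interval over the libraries of -8.32 to 5.62, against 69.7 for Spp1), and this argues against osteoclasts as the whole source. Mmp9, also a neutrophil gene, is left out of this sum, and since the osteoclast gene Ocstamp rose from 1.35 to 3.02 CPM, a small share of them stays open. A difference between tibia and femur marrow that exists without treatment stays open, since 0 libraries of untreated tibia were analysed and the bone cannot be told apart from the treatment. A response of the macrophages to the stromal cells is then a hypothesis that these data leave untested against the bone.

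Granulocyte precursor genes were higher and dendritic cell genes lower in the tibia. A lower share of macrophages, with the other cells unchanged in proportion to each other, would raise both lists. Their gap widened by 0.643 on the log2 scale (0.71 in mouse 7 and 0.58 in mouse 19), and the dendritic cell list was lower in each mouse by camera (adjusted p = 7.4e-05 and 0.0017). This argues against such an even shift as the whole account. A lower share of macrophages with precursors in their place would not raise both lists, so the gap does not speak against it. A higher share of precursors would raise the members of their list that precursors hold at a higher level than the other sorted cells. Of the list, 12 of 16 rose and 0 fell (together 3082 CPM in the femur and 3700 in the tibia). This sum is no measure of precursor RNA, since it holds genes of other lists, such as Calr. A higher share of precursors stays open, since the level of these genes in the other sorted cells was not measured. A change of gene expression within the macrophages is a hypothesis that was not tested apart from a change in cell shares.

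The type I interferon, MHC class II and cell cycle lists moved in opposite directions in the mice. Exchanged bone labels in 1 mouse would put its Arg1 the wrong way round, but 6 of 6 tibia libraries lay above every femur library (18.3 CPM at the lowest against 0.491 at the highest), which argues against it. A single deviating library is argued against as well, since all 3 lists kept their difference in 12 of 12 fits without 1 library, with adjusted p of at most 0.0081, 0.0158 and 0.0081 with an estimated correlation. A difference in sorting or library preparation between the bones of 1 mouse stays open, and so does a difference between the animals themselves, since both bones of only 2 mice were analysed.

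The tibia effect of further genes differed between the mice by the edgeR test of the difference itself, given here as mouse 19 minus mouse 7 on the log2 scale. Among the genes named for the size of their change over both mice the differences were 1.16 for Dab2, 1.31 for Saa3, 0.71 for Ifitm1, 1.01 for Stab1, 0.88 for Cd209a and -0.49 for Ear1. Among macrophage genes and signalling genes they were 0.62 for Mrc1, 0.81 for Il1b, 0.34 for Emr1, 0.35 for Csf1r, 0.71 for Socs3, 1.38 for Tgm2, 0.80 for Maf, 0.45 for Hmox1, 0.56 for Itgb5, 0.55 for Cd300e and 0.24 for Itgal. Among genes of antigen processing, interferon response and lysosome they were 0.54 for Lgmn, 0.35 for Ctss, 0.38 for Oas3, 0.34 for Zbp1, 0.18 for Ctsd, 1.64 for Cxcl10 and 1.61 for Ifit3. Among lipid genes they were -0.53 for Fdps, 0.90 for Apoe, -0.30 for Scd2 and 1.33 for Abca1. The others were 0.26 for Mmp9, -0.37 for Rrm2, 0.17 for Hspa8, -0.26 for Rps2, 0.58 for Il1r2, -0.39 for Prtn3, 0.99 for Thbs1, 0.42 for Ccr3, 1.07 for Flt1, 1.54 for Tppp3, -1.13 for Epx, -0.97 for Chn2, -0.97 for Nrg2, -0.94 for Prg2 and -0.90 for Hal. In all, 44 of the 127 genes of the naming rule differed. Such a difference can lie in the untreated femur as well as in the treated tibia, as shown above for Maf and Itgb5.

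By camera, the genes of 21 lists differed between the mice in their tibia effect relative to other genes, and 12 of these calls held with an estimated correlation. The differences of list medians, mouse 19 minus mouse 7, are given for size and were not themselves tested. For those 12 they were 0.50 for classical activation, 0.17 for alternative activation, 0.21 for resident macrophages, 0.16 for efferocytosis, 0.48 for non-classical monocytes, 0.43 for MHC class II, 0.49 for the type I interferon response, 0.31 for the interferon gamma response, -0.28 for cholesterol synthesis, 0.12 for iron and heme handling, 0.28 for matrix remodelling and -0.27 for cell cycle. The others, with their adjusted p with an estimated correlation, were 0.058 for classical monocytes (0.161), 0.11 for NF-kB and TNF (0.326), -0.045 for oxidative phosphorylation (0.469), 0.063 for lipid handling (0.136), 0.073 for lysosome (0.240), 0.22 for chemokines (0.0693), -0.076 for the unfolded protein response (0.212), 0.21 for neutrophils (0.240) and -0.41 for erythroid genes (0.411).

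In 4 of 262 groups of 6 libraries 1 library stood apart by Dixon's ratio, above its 95% critical value. Chance flags about 1 in 20 groups of alike libraries, which would be 13.1 here, but each group mixes the mice, whose difference widens its range and can hide a library that stands apart, so the number is not compared with chance. Hspa1a in the femur had a ratio of 0.649, from femur library 1 of mouse 19 at 38.2 CPM against 27.4 for the next. Ctsl in the tibia had 0.643 (tibia library 2 of mouse 19, 118 against 101 CPM), Ckb in the femur 0.641 (femur library 3 of mouse 7, 17.8 against 23.2 CPM) and Ccne1 in the tibia 0.735 (tibia library 1 of mouse 19, 35.9 against 32.9 CPM).

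Chance in the grouping of single libraries can be excluded for the genes called between tibia and femur: 1 of 100 splits gave as many, the real one with 850, and the highest of the others gave 15. It can be excluded in the same way for the difference between the mice (1 of 100 splits, 560 genes against 87). These splits part libraries of 1 bone, which are not separate animals, and so do not speak for bones or mice. Whole bones allow 2 splits beside the one by mouse, too few for a share under 0.05, with 850 genes in the real one and 206 in the other, and for the difference they allow 0 others. For the number of gene lists called, chance cannot be excluded, since 7 of 100 splits gave at least the real 19 and the highest other gave 24. The other split of whole bones, which crosses the mice, gave 21 lists. Fitted with the mouse as a term, it sets the tibia of 1 mouse and the femur of the other against the remaining bones. It thus measures the difference of the tibia effect between the mice described above, and is no separate evidence. Within mouse 7 (1149 genes, highest other split 0) and mouse 19 (610 genes, highest other split 1) the 10 splits are too few for a share under 0.05.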

How the results depend on the processing

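The fit on halved counts was chosen after the data were seen, and all other alternatives before. Of 850 genes called between tibia and femur, 838 kept their call with median-of-ratios scaling, 804 with no low-count filter, 801 with the stricter filter, 825 without the 50 most abundant genes in the library sizes, 843 with DESeq2, 816 with limma-voom, 847 with 1 mean per mouse and bone, 832 with a random block and 838 on halved counts. The random block estimated a correlation of -0.0103 between libraries of 1 bone of 1 mouse. That fit is thus close to limma-voom without a block and is no check on treating these libraries as separate. On sums per animal 62 of the 850 genes kept their call. The numbers of the libraries do not pair them. Same-numbered libraries of a mouse had correlations of -0.05 to 0.00059, and 0 of 12 correlated best with their own number. A block on that number gave 239 higher and 256 lower genes, fewer residual degrees of freedom being part of its construction. Without the mouse term 50 were higher and 24 lower, on sums 48 and 17, against a fold of 1.5 17 and 2, and in mouse 19 alone 214 were lower. A test against a fold of 1.5 asks for larger changes, while the median change among the 850 genes was 0.205 on the log2 scale. Sums and mouse 19 alone leave fewer residual degrees of freedom. Without the mouse term the difference between the mice enters the residual spread. How much each of these lowered the counts was not tested.

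On sums per animal the counts were 142 and 74 with no filter, 18 and 3 with the stricter filter, 26 and 8 with DESeq2, 12 and 2 against a fold of 1.5 and 25 and 7 on halved counts; the cause was not tested. Against a fold of 1.5, mouse 7 gave 14 and 2, mouse 19 gave 34 and 2, and the difference 14 and 0. For lists, an estimated correlation left 1 higher and 1 lower, fry gave 5 lower, no mouse term 3 lower, and mouse 19 alone 20 higher and 5 lower.

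Tgfb1, at -0.00063, turned positive with no filter (0.0018), the stricter filter (0.0014), library sizes without abundant genes (0.0024), on sums (7.8e-05), in mouse 7 alone (0.0090) and in mouse 19 alone (0.0010). In mouse 7 alone Il1b (-0.031), Csf1r (-0.13), Ctss (-0.057) and Bank1 (-0.16) reversed. In mouse 19 alone Emr1 (0.12), Itgal (0.0045), Oas3 (0.0063), Zbp1 (0.010), Rrm2 (-0.0028), Btg2 (0.024), Il7r (0.093), Vim (-0.0195), Runx2 (0.0041) and Flt1 (0.10) reversed. Lists are taken as reversed where the direction of camera's test turned, and their medians are given, which can keep their sign. With no mouse term these were megakaryocytes (-0.13) and osteoclasts (-0.018), and with the stricter filter alternative activation (-0.0083). In mouse 7 alone they were classical activation (-0.20), alternative activation (-0.069), resident macrophages (-0.12), efferocytosis (-0.031), MHC class II (-0.21), NF-kB (-0.042), lipid handling (0.0064), iron handling (-0.033), chemokines (-0.086) and neutrophils (-0.013). In mouse 19 alone they were non-classical monocytes (0.17), type I interferon (0.19), interferon gamma (0.083), cholesterol synthesis (-0.0058), cell cycle (-0.067), p53 targets (0.030) and megakaryocytes (0.083).

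Without 1 library, the higher and lower counts ran from 284 to 498 and 279 to 490 over both mice, 9 to 137 and 2 to 57 on sums, 314 to 602 and 381 to 621 in mouse 7, 226 to 365 and 116 to 369 in mouse 19, 251 to 310 and 147 to 234 for the difference, and 9 to 13 and 8 to 10 for lists. Reversals among these fits were Bank1 (-0.039 to 0.070), Btg2 (-0.14 to 0.019), Csf1r (-0.00057 to 0.056), Tgfb1 (-0.018 to 0.0094), Tnf (-0.14 to 0.0051), and the lists of NF-kB (-0.025 to 0.046), alternative activation (-0.022 to 0.057), MHC class II (-0.071 to 0.022), dissociation stress (-0.022 to 0.11), megakaryocytes (-0.20 to -0.11), p53 targets (-0.080 to 0.0083) and resident macrophages (-0.051 to 0.017). Of the genes of the naming rule, 24 lost a call without at least 1 library (adjusted p of 0.0515 to 0.158).

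Other values for single genes kept their direction. Among genes that passed, they stayed past the threshold in 1286 values and lost it in 337 under the settings other than leaving out 1 library. These settings include each mouse alone. Without 1 library the numbers were 1207 and 149. Genes under about 1 CPM, such as Nos2 in the femur, are limited by counting error.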

Other observations

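The genes in this part were picked after their values were seen, and their calls were not repeated without single libraries. They are outside the fixed lists, are not a tested group, and were called by the edgeR quasi-likelihood test. F11r, a junctional adhesion molecule, rose from 21.0 to 39.1 CPM (log2 0.88 ± 0.07, adjusted p = 5.1e-09, 4.0e-04 on sums per animal). Cd38, an enzyme that breaks down NAD, rose from 23.9 to 40.1 CPM (0.75 ± 0.07, adjusted p = 8.8e-08, 0.0058 on sums), and Cmklr1, the receptor of chemerin, from 13.5 to 25.8 CPM (0.95 ± 0.12, adjusted p = 2.2e-05, 0.0383 on sums). Ecm1, an extracellular matrix protein, rose from 31.9 to 56.1 CPM (0.85 ± 0.11) and Slc39a14, a zinc and iron transporter, from 5.10 to 10.1 CPM (0.97 ± 0.13), with 0.0378 and 0.0157 on sums.

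Genes at lower levels were picked in the same way. Tmem119 rose from 3.35 to 6.51 CPM (log2 0.96 ± 0.15, edgeR adjusted p = 3.1e-04, 0.0383 on sums per animal) and Olfml3 from 0.337 to 1.53 CPM (2.18 ± 0.43, adjusted p = 0.0025, 0.0399 on sums). Fcrls rose from 0.102 to 0.996 CPM (3.18 ± 0.56, adjusted p = 8.4e-04) and narrowly missed the threshold on sums (0.0501). In mouse 7 and mouse 19 Tmem119 changed by 0.88 and 1.04. Olfml3 had 83 against 14 counts in mouse 7 (ratio 6.03, 95% interval 2.72 to 16.1) and 39 against 11 in mouse 19 (3.13, 1.14 to 8.95), where it did not pass (adjusted p = 0.183). Fcrls had 49 against 8 counts in mouse 7 (6.23, 2.20 to 25.1) and 30 against 0 in mouse 19, where the 95% interval of the ratio begins at 3.16.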
